A study of Mus musculus with 10 samples.

How the data were processed

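The study measured m6A in polyadenylated RNA of mouse cortex and hippocampus at postnatal day 5, in WT animals (3 IP and 3 input libraries) and in animals with a Nestin-Cre driven knockout of Mettl14 (2 IP and 2 input libraries). Per the labels, RNA was taken up in Trizol, an anti-m6A antibody was used before library building for the IP samples, and libraries came from a stranded mRNA kit. The labels also name a serum-free culture medium under growth conditions, while the tissue label names cortex and hippocampus, so whether RNA came from tissue directly or from cultured cells cannot be settled from the labels. Per the submitters' processing notes, STAR and the genome build GRCm38 were used, without versions. The peak caller, its thresholds, its annotation and the way libraries of a genotype were combined are not given in the sources used here.

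The authors deposited a consensus peak list for each genotype. Each entry gives a position, a strand, a gene symbol and the exonic blocks of the peak, and the deposited score of each peak was read as the caller's p-value or q-value, since every score lay between 0 and 0.00015. Which of these it is, is not stated. Scores of 764 WT and 80 KO peaks are listed as 0, too small to be held. P-values were used to describe, rank or filter peaks within a list. A further count, fixed beforehand, sets the KO median as a threshold on both lists, which come from unequal numbers of libraries, so it compares p-values of unequal power. A comparison of KO p-values with the 90th percentile of the WT list, chosen after seeing the data, has the same limit. With no values per library there was no replicate error, no leave-one-out fit and no expression level, so whether a peak is listed cannot be separated from how strongly its gene was expressed. The depth of the libraries is unknown here. Nothing in the sources says how the libraries of a genotype relate to separate animals.

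Samples were grouped by the genotype and treatment labels. Before the data were examined, the tests, the alternatives, 22 gene lists and the rule for named genes were fixed. Entries start counts at 0, since 199 WT and 61 KO entries start 1 base before the start of their gene as counted from 1, and all printed coordinates count from 1. Entries of a list that overlapped by exonic blocks on the same strand were merged, which took 15091 WT entries to 15009 peaks and 3733 KO entries to 3673, of which 60 and 17 carry more than 1 gene name. A WT peak was called retained when a KO peak covered at least 1 of its exonic bases on the same strand. Gene spans, gene types and synonyms came from a RefSeq gene table of GRCm38.p6, in which 99.9% of WT and 99.8% of KO gene names were found, and 99.8% and 99.7% of entries lay inside their gene. Of the genes in the fixed lists, 604 of 616 were found in it.

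For each list, the number of genes with a retained peak, among those with a WT peak, was compared with 10000 random lists drawn from all genes with a WT peak and matched on the number of WT peaks (1, 2, 3, or 4 and more). P-values were two-sided and adjusted by Benjamini-Hochberg over the 19 lists with at least 5 such genes. Where the central 95% of random lists began at 0, a low number of retained genes could not pass. The lists covered m6A writers and readers, 7 groups of nuclear genes of mitochondria, mitochondrially encoded genes, ribosomal proteins, progenitor, synaptic, chromatin and activity genes, and markers of neurons, astrocytes, oligodendrocytes, microglia, vessels, meninges and blood. A union of the microglia, vessel, meningeal and blood markers, without genes of the choroid plexus epithelium, stood for cells outside the Nestin lineage. Widths were compared by a permutation test with 100000 permutations and positions by Fisher's exact test, both two-sided. Shares carry Wilson 95% intervals. Genes and peaks are not replicates, so each test describes these 2 lists and not the animals.

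Named genes were Mettl14 and the machinery genes with a peak, the 10 genes with most WT peaks and no KO peak, the 10 with most KO peaks among those with a retained peak, the 10 with the longest KO exonic peak length and no WT peak, and, in each list, up to 2 genes with most WT peaks and no retained peak and up to 2 with most KO peaks and a retained peak. Ties went to summed exonic length, and genes with Gm or Rik names were left out. Genes named beyond this rule are said to be so where they appear, and some genes that the rule takes are not reported here.

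Planned analyses of the DRACH motif, of untranslated regions, coding sequence and stop codons, of genes assigned by exon overlap, of another transcript model and of KO peaks moved within exons were not run, since they need a genome sequence or exon annotation not used here. Distances to the gene start (200 bases) and gene end (1000 bases) replaced the transcript classes, and moves of single-block KO peaks along the chromosome replaced the moves within exons. These replacements were chosen after seeing the data. So were the removal of recurring p-values (those held by at least 30 KO entries), the matching on the best p-value and the union of mitochondrial lists. The distance between peak midpoints and the comparison of strong and weak peaks within classes of width (pooled by the Mantel-Haenszel method) were also added then. The same holds for the comparisons of markers inside and outside the Nestin lineage, by list and together, and for the shares by gene type and by number of blocks. Other settings, fixed beforehand, changed the overlap asked for, strand, peak body, merging, list length, strength, matching and the definition of retained.

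Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used, with bedtools 2.31.1 as a check of the overlaps, which differed on 0 peaks. The overlap and the list test were tested on simulated data for the comparison of WT with KO peaks. In a list simulated from the 15009 WT peaks, about 20% of them were kept at random, regardless of strength, width and gene. Of the peaks kept, 100% were found, and 0% of the others. Each kept peak was the longest block of its WT peak, slightly moved, so this outcome was largely fixed in advance. It checks the code and not how far real KO peaks lie from WT peaks. Of 200 random lists of 40 genes drawn from the 7717 WT genes, 2.5% had a permutation p below 0.05, and 100% of 40 lists with 24 planted retained genes did. These checks do not cover retention that depends on peak strength or width. They also do not cover lists with fewer than 40 genes with a WT peak, as most of the tested lists were.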

Results

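Methylated RNA was mapped by m6A-seq in cortex and hippocampus of mice at postnatal day 5. In this assay an antibody against N6-methyladenosine (m6A) pulls down RNA fragments, and regions enriched over unselected input RNA are called as peaks. METTL14 is the partner of METTL3 in the nuclear complex that writes most m6A on mRNA. The knockout (KO) removed Mettl14 with Nestin-Cre, a recombinase active in the neuroepithelial lineage that gives rise to neurons, astrocytes and oligodendrocytes. The 10 samples were 3 IP and 3 input wild-type (WT) libraries and 2 IP and 2 input KO libraries. Whether their RNA came from tissue directly or from cultured cells cannot be settled from the labels. The values analysed were 2 consensus peak lists, a single list per genotype, so no difference between the genotypes has a replicate error. The depth of the libraries is unknown here, and intervals cover counting error over peaks or genes only. Coordinates are those of the mouse build GRCm38, counted from 1.

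The comparison of both lists asked which m6A peaks of the developing brain were still listed without Mettl14. Mettl14 itself carried 1 WT peak, of 180 exonic bases, on chromosome 3 from 123369398 to 123369577 on the minus strand, inside the gene, and no KO peak. Which part of the gene was deleted is not given in the sources used here, and a missing peak does not measure its expression. Genes dense in WT peaks and without any KO peak were led by Fem1a, a substrate receptor of a cullin ubiquitin ligase, with 12 WT peaks over 2464 exonic bases on chromosome 17. Pdzd2 followed with 10 WT peaks. Bahcc1, the brain-enriched ubiquitin ligase gene Trim67, the cytoskeletal linker gene Dst, the zinc finger factor gene Hivep2 and the transcriptional coregulator gene Tcf20 had 9 each. Apc, a negative regulator of Wnt signalling, and Ankrd50 had 8 each.

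The WT list held 15009 peaks in 7717 genes and the KO list 3673 peaks in 2879 genes, a ratio of 4.09 in peaks. The ratio was 6.43 among peaks at least as strong as the median p-value of the KO list, although p-values of lists from unequal numbers of libraries are not strictly comparable. Of the WT peaks, 1933 were overlapped by a KO peak on the same strand, which is 12.9% (Wilson 95% interval 12.4 to 13.4), and 13076 were not. These are called retained and lost below. In the other direction, 57.1% of the KO peaks (2096, interval 55.5 to 58.7) lay over a WT peak. Peaks were listed in WT alone for 5637 genes, in both lists for 2080 genes and in KO alone for 799 genes. A retained peak was found in 1588 genes, 20.6% of the genes with a WT peak. KO peaks were narrower, with a median exonic width of 151 bases (quartiles 120 and 210) against 208 bases (121 and 328), and their summed exonic length was 650.0 kb against 3914 kb. Both shares depended on the overlap asked for and on the length of the WT list. The WT and KO shares were 6.26% and 25.6% when at least 50% of both peaks had to be shared, and 28.6% and 32.5% when the WT list was shortened to its 3673 strongest peaks. The gene counts depended on list length too. With the shortened WT list, more genes had peaks in KO alone than in WT alone, since fewer WT peaks enter.

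Some transcripts kept many of their peaks in the KO list. Meg3, a maternally expressed imprinted long noncoding RNA on chromosome 12 (109540996 to 109571729), had 9 WT peaks, of which 7 were retained, and 9 KO peaks. A Meg3 peak from 109560382 to 109560622 had the same borders in both lists. Nfix, which encodes a nuclear factor I transcription factor of neural progenitors, retained 6 of 7 WT peaks, and the microtubule-associated protein gene Map1b 5 of 9. Agap2 retained 4 of 5, Lmtk3 3 of 4, the brain homologue of Apc, Apc2, 4 of 7, and Auts2 3 of 5. Retention was partial in genes with many WT peaks, with 3 of 10 in Tnrc18 and 4 of 14 in Plec, which encodes the cytoskeletal linker plectin. A KO peak often covered only a part of the WT peak. From WT to KO, summed exonic peak length went from 6053 to 1173 bases in Apc2 and from 6701 to 1056 in Plec. It went from 3505 to 1383 in Lmtk3, and fell in each gene named here except Meg3 (2948 and 3067). The genes were taken by their number of KO peaks, so their high counts follow in part from that choice.

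**Figure D1:**
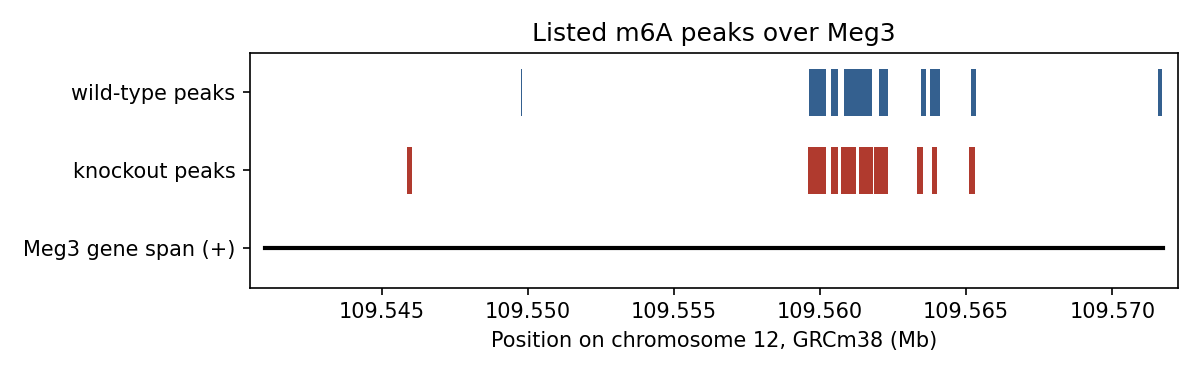
Exonic blocks of the listed peaks over Meg3, by position on chromosome 12 (GRCm38, in Mb), with WT peaks in the top row, KO peaks in the middle row and the span of the gene as a black line. Of the 9 WT peaks, 7 are overlapped by a KO peak, and all 7 lie between 109559633 and 109565330.

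Transcripts of the m6A machinery followed both courses. Among writers and cofactors, 8 of 12 genes had a WT peak and 2 of these a retained peak, against a mean of 1.67 in matched random lists (adjusted permutation p = 1). Zc3h13, a scaffold of the writer complex, retained 3 of 5 peaks and Rbm15b 2 of 3. Mettl14, Mettl16, Pcif1, Rbm15, Virma and Wtap retained none. Among readers and erasers, 10 of 14 genes had a WT peak and 5 a retained peak (random mean 2.95, adjusted permutation p = 0.799). The nuclear reader gene Ythdc1 retained 2 of 4 peaks, Prrc2a 4 of 7, and Fmr1 and Hnrnpa2b1 1 of 2 each, while the single peak of Hnrnpc, on chromosome 14 from 52075051 to 52075414, had the same borders in both lists. The cytoplasmic reader genes Ythdf1, Ythdf2 and Ythdf3 had 3, 2 and 3 WT peaks and none in the KO. Of the demethylase genes, Fto had 1 WT peak and no KO peak, and Alkbh5 had 4 WT peaks, none of them retained, and 1 KO peak elsewhere in the gene.

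Neuronal and chromatin genes had retained peaks more often than matched genes did. Of the 10 neuron marker genes with a WT peak, 8 had a retained peak, among them Rbfox3, which encodes the nuclear protein NeuN (3 of 3 peaks), Elavl3 (2 of 5) and, named after its values were seen, Stmn2 (1 of 1). Slc32a1 and Slc17a6, which encode vesicular transporters for inhibitory transmitters and for glutamate, had 3 and 1 WT peaks and none in the KO. Synaptic and axonal genes had a retained peak in 27 of 48, among them Map1b and the postsynaptic scaffold gene Shank1 (3 of 4 peaks), while Ephb2 and Ank3 retained none of 6 peaks each. Chromatin and histone modifier genes had one in 26 of 44, among them Auts2, while the histone methyltransferase gene Kmt2d retained none of 15 peaks and Asxl1 none of 6. Random lists matched on the number of WT peaks per gene gave means of 2.95, 16.5 and 16.3 genes. Each of these 3 lists had an adjusted permutation p = 0.0190, two-sided, over 19 lists tested. The adjusted permutation p ranged from 0.00380 to 0.304 for neuron markers and from 0.00190 to 1 for each of the other lists over the alternatives, and no list passed once genes were also matched on their best WT p-value, a matching chosen after seeing the data. With at least 50% of both peaks shared, or with the stronger 50% of each list alone, the neuron markers were the only list that passed.

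**Figure D2:**
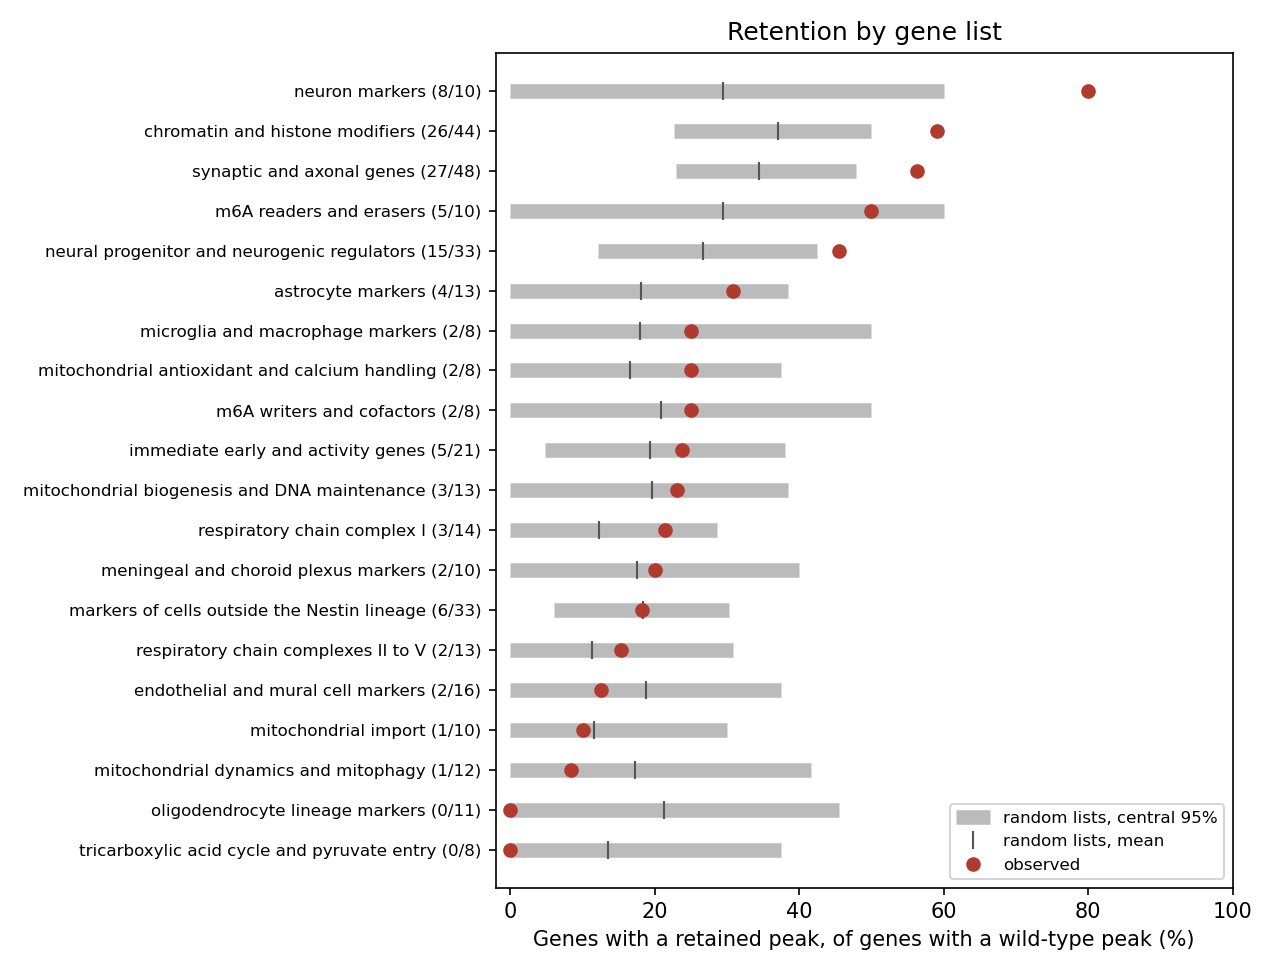
Share of genes with a retained peak among the genes of each fixed list that had a WT peak (x axis, in percent; counts beside each name). Red points are observed shares, and grey bars and ticks give the central 95% and the mean of 10000 random lists matched on the number of WT peaks per gene. Neuron markers (8 of 10), chromatin and histone modifiers (26 of 44), synaptic and axonal genes (27 of 48) and progenitor regulators (15 of 33) lie to the right of their bars, the last with an adjusted permutation p = 0.109.

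Progenitor regulators, glial genes and activity genes did not pass this test. Neural progenitor and neurogenic regulators had a retained peak in 15 of 33 genes (random mean 8.81, adjusted permutation p = 0.109), among them Nfix and Bcl11b (2 of 4 peaks), while Sox11 retained none of 6 and Cux1 none of 4. Astrocyte markers had one in 4 of 13 genes (2.35, adjusted permutation p = 1), including Sox9 but not Gfap or S1pr1. Oligodendrocyte lineage markers had none in 11 genes (2.34, adjusted permutation p = 0.477), although Cspg4, the NG2 proteoglycan gene of precursor cells, held 7 WT peaks and Olig1 held 3. This is the lowest possible count, and its unadjusted permutation p was 0.126, so low retention could not pass in this list. Immediate early and activity genes had one in 5 of 21 genes (4.07, adjusted permutation p = 1). The single WT peaks of Egr1 and Jund were retained, whereas Myc lost 5 peaks and Nr4a3 lost 4.

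The title of the study names mitochondrial function, and lists of mitochondrial genes were examined for this reason. Nuclear genes of mitochondria had a WT peak in 78 of 220 members and a retained peak in 12 of these 78, close to the mean of 11.4 in matched random lists (permutation p = 0.952, for a union of 7 lists formed after seeing the data). Respiratory chain complex I genes had a retained peak in 3 of 14, among them Ndufb10, whose peak on chromosome 17 from 24722426 to 24722737 had the same borders in both lists, and Ndufb7, while Ndufa13 lost 2 peaks and Ndufv1 lost 1. Complexes II to V had 2 of 13, Cox10 and the ATP synthase gene Atp5g3, with Sdhaf1 and Sco2 among the others. Genes of the tricarboxylic acid cycle and pyruvate entry had 0 of 8, with 2 lost peaks each in Ogdh and Pcx. Mitochondrial dynamics and mitophagy had 1 of 12, Trak2, while Trak1 lost 3 peaks and Mief2 lost 2. Biogenesis and DNA maintenance had 3 of 13, including Nrf1 and the mitochondrial helicase gene Twnk (1 of 5 peaks), while the coactivator genes Ppargc1a and Pprc1 lost 3 peaks each. Import had 1 of 10, Timm44, with Immt and Tomm6 among those without one, and antioxidant and calcium handling had 2 of 8, Letm1 and Slc25a23, but not Micu2. The adjusted permutation p was 1 for each of these 7 lists. No peak of either list lay on the mitochondrial chromosome, so the 15 mitochondrially encoded genes had none. Whether that chromosome was searched for peaks is not given in the sources used here, so this does not show that its RNA lacks m6A. Cytosolic ribosomal protein genes had a WT peak in 4 of 45 members, none retained and too few to test.

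Markers of cells that Nestin-Cre does not target were examined because such cells would keep METTL14. How many such cells the samples held is unknown, since the labels do not settle whether RNA came from tissue or from culture. Their union had a retained peak in 6 of 33 genes, against a mean of 6.05 in matched random lists (permutation p = 1). Microglia and macrophage markers had one in 2 of 8, the fractalkine receptor gene Cx3cr1 (1 of 2 peaks) and Siglech (1 of 1), while C1qa and Sall1 had none. Endothelial and mural cell markers had one in 2 of 16, the endothelial cadherin gene Cdh5 (2 of 3 peaks) and Notch3, while the glucose transporter gene Slc2a1 lost 4. Meningeal and choroid plexus markers had one in 2 of 10, the collagen genes Col4a1 and Col6a1, while Foxc1 lost 3 and Col5a1 lost 2. The adjusted permutation p was 1 for each of these lists. Blood cell markers had no WT peak. Cspg4, in this union as a mural cell gene, is also in the oligodendrocyte list.

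Retained peaks were stronger and wider in the WT list than lost ones. By the p-value that the authors listed, 30.9% of the strongest 20% of WT peaks were retained (interval 29.3 to 32.6), and 14.0%, 9.49%, 6.40% and 3.53% (interval 2.93 to 4.25) in the following classes. Retained peaks had a median exonic width of 359 bases and lost peaks of 181 bases, a difference of 178 bases (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The difference was 89 bases when 50% of both peaks had to be shared. In a comparison added after seeing the data, 52.7% of retained and 19.2% of lost peaks lay on 2 or more exonic blocks (Fisher's exact p = 1.42e-199). Strong peaks were also wide, and a wide peak offers more bases to overlap. A comparison added after seeing the data was made within 5 classes of width and pooled over them. The strongest 40% of WT peaks were retained 1.95 times as often as the weakest 40% (95% interval 1.66 to 2.28). Without width classes the ratio was 4.53. By class it rose from 0.932 in the narrowest to 2.95 in the widest. The widest class ran from 360 to 4019 bases, so width was not held equal within it. The shares were 34.6% and 11.7% in the widest of 5 width classes and 2.60% and 2.79% in the narrowest.

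**Figure D3:**
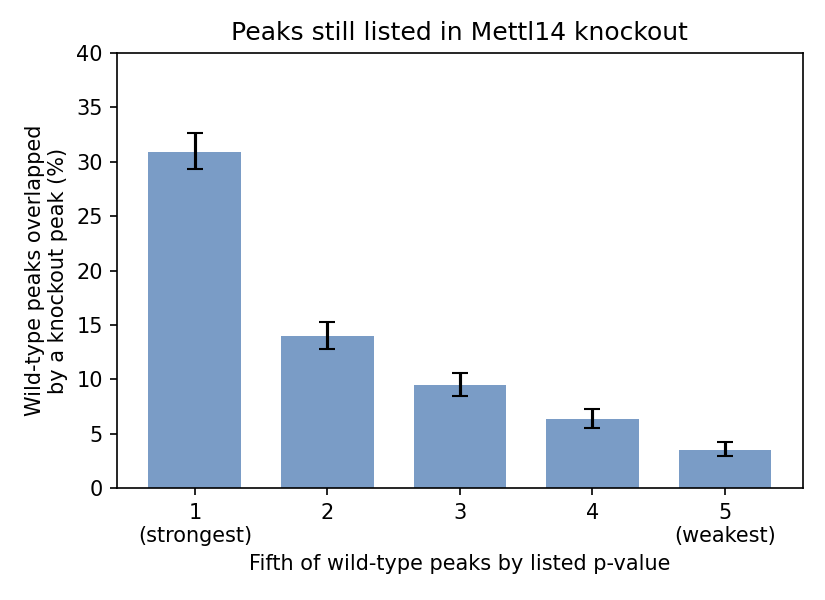
Share of WT peaks overlapped by a KO peak (y axis, in percent) in 5 equal classes of WT peaks ordered by their listed p-value, from the strongest (1) to the weakest (5). Bars give the share and error bars the Wilson 95% interval, and the share falls from 30.9% to 3.53%.

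Lost WT peaks lay more often near the end of their gene than retained ones, while the KO list as a whole did so about as often as the WT list. Of the lost peaks, 17.5% had their midpoint within 1000 bases of the gene end, as for the last of the 12 Fem1a peaks, against 8.91% of the retained peaks. The difference of -8.60 percentage points had an adjusted Fisher's exact p = 1.09e-23, two-sided, and was -5.26 points with a window of 500 bases and -15.5 points with 5000 bases. It was negative in each of the 5 classes of WT strength, though not past the threshold in the weakest class (-5.57 points, Fisher's exact p = 0.126). Retained peaks were also wider than lost ones and lay more often on several exonic blocks. The difference near the gene end was not tested at equal width or equal number of blocks, so a part played by either stays open. Of all peaks, 16.6% in the KO list (interval 15.4 to 17.8) and 16.4% in the WT list (15.8 to 17.0) lay near the gene end, with 8.31% of KO peaks over a WT peak and 18.6% of KO peaks elsewhere in a gene with a WT peak. Near the gene start, within 200 bases, the shares were 4.09% and 4.50% (adjusted Fisher's exact p = 0.442), and the sign of this difference changed with the settings. The classes come from the ends of each gene's span, and the windows at the gene end were chosen after seeing the data. They do not tell untranslated from coding sequence.

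KO peaks in genes without any WT peak numbered 836. By exonic length they were led by Kcnq1ot1, an imprinted long noncoding RNA antisense to Kcnq1, with 3 peaks over 872 bases on chromosome 7, the longest from 143242473 to 143242892, though whether reads were assigned by strand is not given in the sources used here. AF366264 followed with a single peak of 805 bases on chromosome 8 from 13835558 to 13836362, then Cytip (719 bases), the pituitary transcription factor gene Pou1f1 (654), the B cell factor gene Pax5 (632) and Usp17la (598), a member of a family of close copies whose reads are hard to assign. Aqp7 (596), the cell cycle kinase gene Cdk6 (571), Runx3 (510) and Klhl31 (482) completed the 10 longest. Of these 836 peaks, 16.6% lay in long noncoding RNA genes (interval 14.3 to 19.3) against 1.63% of all WT peaks (1.44 to 1.84), and 35.6% near a gene end (32.4 to 38.9) against 16.4% (15.8 to 17.0). Without peaks at 8 p-values that recur in the KO list, a filter chosen after seeing the data, genes with peaks in KO alone fell from 799 to 444.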

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

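No paired analysis was possible because the lists hold no values per library, and leaving out a replicate was not run for the same reason. Alternatives that need exons or sequence were not run, and keeping autosomes and X alone moved no peak. Ignoring strand, using whole spans, allowing a gap of 100 bases or leaving entries unmerged kept both overlap shares within their intervals. The WT share of 12.9% moved to 6.83% when 50% of the peak had to be covered, 6.26% for 50% of both peaks, 28.6% with the WT list shortened to the KO number and 14.2% with the stronger 50% of each list. The KO share of 57.1% moved to 54.0%, 25.6%, 32.5% and 61.7% in the same order. It was 64.0% without recurring p-values. For single-block KO peaks alone it was 51.7% in place and 25.1% and 17.8% after moves of 300 and 500 bases, which can leave the exon. These settings were added after seeing the data. At the KO median p-value or stronger, 11871 WT and, by construction, 1847 KO peaks remained, a ratio of 6.43 against 4.09. Shortening the WT list gave 1460 genes in WT alone, 1238 in both and 1641 in KO alone, and the stronger 50% of each list gave 3672, 1113 and 424. Genes in KO alone numbered 444 without recurring p-values. These counts move by construction, since fewer peaks enter. Near the gene start, the difference of -0.41 points was -0.98 with a window of 100 bases (adjusted Fisher's exact p = 0.000876), and turned to 0.89 with the stronger 50% of each list (p = 0.0453) and to 1.97 with 50% of both peaks (p = 0.00676). The cause was not tested, and no direction is drawn there. The lower share of retained peaks near the gene end kept its direction under every alternative run and its side of the threshold under those with a test, which the share of exonic bases (-8.08 points) did not have. The width difference was 89 bases in its only alternative, 50% of both peaks (permutation p = 0.0005, the smallest that its permutations can give). The 3 lists past the threshold fell to 1 with 50% of both peaks, 1 with the stronger 50% and 0 when matched on best p-value, the last added after seeing the data, and the cause was not tested. Retained genes minus the random mean changed sign for lists that had not passed the test. Cells outside the Nestin lineage, at -0.05, gave 0.847 with any KO peak in the gene, 0.179 matched on length and 1.61 matched on best p-value. Any KO peak in the gene gave -0.186 for m6A writers, -0.298 for complexes II to V and -0.312 for the mitochondrial union. Unmatched lists gave -0.673 for complexes II to V, -4.07 for the mitochondrial union and -0.0446 for meningeal markers. With 50% of both peaks, activity genes gave -1.15 and meningeal markers -0.909, and matching on length gave -0.359 and -0.218. The stronger 50% gave -0.275 for progenitor regulators, which passed with any KO peak in the gene (adjusted permutation p = 0.0304) and against unmatched lists (0.0114), and -0.135 for meningeal markers. Retained counts of 15 of 97 named genes left their interval with 50% of the peak covered and 17 with 50% of both. The unknown depth of the libraries limits what a lost peak can show.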

Other observations

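Some genes of the fixed lists had a KO peak and no WT peak, and they were named after their values were seen. Among synaptic genes these were the glutamate receptor genes Gria3 (2 KO peaks) and Grin2a (1) and the scaffold gene Dlg2 (1). The neuron marker Thy1, the myelin gene Mog, the ribosomal protein genes Rpl4 and Rps14, the chromatin gene Tet1 and the progenitor list's Tcf7l2 had 1 each. Among markers of other cells, the smooth muscle actin gene Acta2 had 2, and Flt1, Lpl, Runx1, Tgfbr1, Col1a1 and the T cell gene Cd3e had 1 each. The pyruvate dehydrogenase kinase gene Pdk4 and Suclg2 of the tricarboxylic acid cycle had 1 each.

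KO peaks lay close to the centre of the WT peaks they met. In 835 pairs of a single-block WT peak with a single KO peak, the midpoints lay a median of 45 bases apart. Random placement of overlapping peaks gave a median of 112 bases, and the lowest of 10000 draws was 98.5, though the draws ignore exon borders, which also hold peaks together. The share of genes with a retained peak was 10.5% for genes with 1 WT peak, 22.7% with 2, 33.8% with 3 and 46.0% with 4 or more. Any retained peak counts for a gene, so a rise with the number of peaks follows from the definition.

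The tests in the following paragraphs were chosen after the result was seen, except the comparisons of neuron markers and of markers outside the Nestin lineage with random lists, whose tests were fixed before but whose bounds were not, and the matching on best p-value, whose bounds were written before its result was seen.

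KO peaks in genes without a WT peak, such as those of Runx3 (p-values of 1.3e-11 and 6.3e-15), may in part rest on sparse evidence. Of these peaks, 45.8% had one of 8 recurring p-values, from 9.1e-07 to 3.2e-18 in log10 steps of 1.60 to 1.71. The share was 2.34% of KO peaks over a WT peak, a ratio of 19.6 (95% interval 14.7 to 26.1). Those peaks were stronger, with a median listed p-value of 1.6e-19, beyond the recurring values. A closer match was KO peaks elsewhere in a gene with a WT peak (median 1e-12 against 1.3e-12), with a share of 6.88% (interval 5.27 to 8.94). Even steps between the recurring values could come from counts growing by 1, but the caller is unknown and this was not tested. Weak peaks missed in WT are left open. Of the KO peaks in genes without a WT peak, 34.0% had a p-value above the 90th percentile of the WT list, but p-values of lists from unequal numbers of libraries are not comparable. A true gain of m6A without Mettl14 was not tested.

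For the retained peaks of neuron marker genes, cells outside the Nestin lineage are argued against as the only source, provided that the overlaps are m6A. Such cells are not expected to express neuron markers. Yet 8 of 10 of these had a retained peak, against a mean of 2.95 in matched random lists (adjusted permutation p = 0.0190). Chance overlap and antibody binding without m6A were not excluded, and each would remove this argument. The neuron markers lay at or above the 99.4th percentile under every alternative run, though the adjusted permutation p was 0.304 when matched on best p-value. Set directly against the 6 of 32 markers of outside cells, a comparison chosen later, the neuron markers did not pass (permutation p = 0.0973, adjusted over 3 lists), and neither did 12 of 33 markers of neurons, astrocytes and oligodendrocytes together (permutation p = 0.44), both matched on the number of WT peaks. A contribution of outside cells stays open, as their markers lay at the 50.4th percentile of matched random lists, and 0 of 11 oligodendrocyte markers had a retained peak. Chance overlap of clustered peaks stays open: single-block KO peaks lay over a WT peak in 51.7% in place and in 25.1% and 17.8% after moves of 300 and 500 bases both ways, but a moved peak can leave its exon, where no peak is listed. The median distance of 45 bases between midpoints, against 98.5 in the lowest random draw, goes against overlap at random places, but those draws ignore exon borders as well. Lower power of the KO list (2 pairs of libraries against 3) stays open too. The strongest 20% of WT peaks were retained 8.76 times as often as the weakest 20%. But pooled within classes of width the ratio for the strongest and weakest 40% was 1.95, and it was 0.932 (interval 0.467 to 1.86) in the narrowest class. An incomplete loss of m6A, m6A from other enzymes and antibody binding without m6A were not tested.

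The high retention in neuron, synaptic and chromatin genes could come from stronger WT peaks in these genes. Matched on best p-value and number of peaks, 2 of the 3 lists stayed above the central 95% of random lists, the neuron markers at the 99.4th percentile and the chromatin genes at the 98.9th, while synaptic genes lay at the 91.7th. The adjusted permutation p then ranged from 0.304 to 0.830, and with some lists above and another within the random range, peak strength and membership of the lists cannot be told apart here. Expression was not used here and remains open.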
